A study of Mus musculus
Rattus rattus and Mus musculus and Homo sapiens with 4 samples.

How the data were processed

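RNA sequencing was done on 4 libraries, 1 per group: dorsal root ganglia (DRG, the sensory ganglia beside the spinal cord) of wild-type C57BL/6 mice, and the cell lines F-11, ND7/23 and SH-SY5Y. Per the labels' protocols, whole ganglia from lumbar levels were kept in RNAlater, the cultured cells were trypsinised and pelleted, and total RNA was taken up with the RNeasy Mini kit. Reads were single-end and 100 nucleotides long. Per the submitters' processing notes, CASAVA 1.8.2, TopHat, Cufflinks and HTSeq were used with the builds mm9, hg19 and rn5; the notes used here do not say which tool did which step. Strand use, the annotation and the handling of reads that align to several places are not given in the sources used here.

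The deposited files are 6 tables of raw counts, with whole-number read counts per gene symbol and 5 summary rows, per the file contents. DRG was counted on mouse genes and SH-SY5Y on human genes. F-11 and ND7/23, which are fusions of mouse neuroblastoma cells with rat DRG neurons, each had a mouse and a rat table. How reads were split between the genomes is not given in the sources used here. A read that aligns to both may stand in both tables, so the tables of a hybrid line may not add up to its number of reads. The summary rows stayed out of the totals. Reads on no gene made up 6.21% (DRG), 7.68% (SH-SY5Y), 7.96% (F-11, mouse), 7.23% (ND7/23, mouse), 14.63% (F-11, rat) and 13.43% (ND7/23, rat) of the assigned, unassigned and ambiguous reads together. Ambiguous reads made up 2.87%, 5.86%, 2.72%, 2.82%, 0.35% and 0.35% in the same order. The row for alignments that were not unique held 0 in each of the 6 tables. In the mouse tables some genes that every cell uses had few counts: Gapdh stood at 1.97 CPM in DRG and at 460 CPM in SH-SY5Y, and mt-Co2 was listed at 0 in F-11. Levels of genes with near-identical copies, among them the ribosomal protein, globin and mitochondrial genes, are therefore uncertain.

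Counts were divided by the total of all gene counts in the table and scaled to the usual unit, CPM (reads of a gene per 1000000 reads on genes). With 1 library per group there is no test across replicates, and no p-value is given. A gene was called higher or lower by size alone, when its CPM differed by 4-fold or more and the higher library reached 1 CPM. A library under 3 counts was set to 3 counts for the ratio. Exact (Clopper-Pearson) 95% intervals were computed for ratios and shares. For ratios they cover counting error only, not variation between animals, cultures or library preparations. For shares of detected genes they treat the genes of the lists as independent draws, which they are not. One CPM was 32.5 reads in DRG, 27.1 in SH-SY5Y, 26.3 in F-11 and 27.7 in ND7/23, and 3 counts were 0.092, 0.111, 0.114 and 0.108 CPM.

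The comparisons were each line against DRG and F-11 against ND7/23. Mouse counts were used for the hybrid lines. Human and mouse genes were matched by symbol without regard to case, which gave 15604 genes. No correction for gene length was made between the species. Before the data were examined, 25 gene lists, a panel of 18 genes, the size rule and the rule for named genes were fixed. Named genes are the panel, the 6 genes with the highest and the 6 with the lowest ratio among genes at 50 CPM or more in the higher library, and the 2 most abundant members of each list. Some genes that the rule takes in are not reported here. Genes named outside this rule were chosen after their values were seen, and the text says so. For each list, the median log2 ratio was set against the medians of 10000 random lists of the same size matched on mean expression in 20 bins. List members were looked up under older symbols where the tables use them, so Piezo2 is listed as Fam38b, Piezo1 as Fam38a and Asic1 as Accn2. Correlations across genes are Spearman's rho of log2(CPM + 1) over genes at 1 CPM in either library.

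The rat share of a hybrid line is its rat count divided by its rat plus mouse count over 15773 genes present under 1 symbol in both tables. Gene order was taken from RefSeq genes on the mouse assembly GRCm38.p6, which is not the build of the files, so it served only to say which genes are neighbours. Of 9399 genes with 100 or more counts in both lines, 9012 had a place in that order.

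The ratios, calls and list percentiles were tested on simulated counts with 200 changed genes among those of the comparison. The correlation between neighbouring genes and the dispersion of trace counts were tested on simulated values. For each of the 4 comparisons, 100% of genes changed 8-fold and 0% of genes changed 2-fold were called, and 0 unchanged genes were called. The simulated counts held counting error only, and the changed genes were not taken from those at low levels. Such results check the calculation and do not give a rate of false calls between real libraries. Alternatives were edgeR TMM factors, DESeq2 size factors, totals without the 50 most abundant genes, other filters, folds and floors, thinning to the smallest total, and summed mouse and rat counts. The planned correction by gene length for SH-SY5Y was not run, because human gene lengths were not used here. Calculations were made with Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and with R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0.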

Results

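Transcriptomes of whole mouse DRG and of 3 cell lines used in place of DRG neurons were compared. SH-SY5Y is a human neuroblastoma line, and F-11 and ND7/23 are hybrids of mouse neuroblastoma cells and rat DRG neurons. Each group had 1 library, so no difference below has a replicate check, and each ratio describes these libraries. Reads on genes numbered 32480739 in DRG, 27118145 in SH-SY5Y, 26346262 in F-11 on mouse genes and 27667233 in ND7/23 on mouse genes. The rat tables held 11545905 reads for F-11 and 10350156 for ND7/23. At 1 CPM or more, 14413 genes were detected in DRG, 12975 in F-11, 13523 in ND7/23 and 15408 in SH-SY5Y, the last on human genes.

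The first comparison asked how far F-11 resembles the ganglion. Scn10a, Scn11a, Trpv1 and Calca, genes that mark nociceptors, the sensory neurons for painful stimuli, were under 1 CPM in F-11. The sodium channel gene Scn10a had 870 CPM in DRG and 0.797 CPM in F-11, a log2 ratio of -10.09 (interval -10.78 to -9.48). Scn11a stood at 473 and 0.19 CPM, the heat-gated channel gene Trpv1 at 147 and 0.152 CPM, and Calca, which encodes the peptide CGRP, at 1802 and 0.987 CPM. Division genes and genes of the sympathoadrenal lineage, from which neuroblastoma arises, were far higher in the line, with Mki67 at 367 against 8.25 CPM and Hand2 at 657 against 0.77 CPM.

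Across 15489 genes at 1 CPM in either library, 2811 were 4-fold higher and 3530 were 4-fold lower in F-11. At 2-fold the order turned, with 5375 higher and 4857 lower. The sodium channel list had a median log2 ratio of -5.63 over 14 measured members, of which 11 were lower and 0 higher. Scn9a, another channel gene of nociceptors, was among the lower ones at 21.0 against 356 CPM, with a log2 ratio of -4.08. Of 65 potassium channel genes, 54 were lower and 0 higher, with a median of -4.37, and Kcna1 stood at 0.797 against 834 CPM. None of the 10000 matched random lists had a median as low as either channel list. The touch receptor gene Piezo2 had 4 counts in F-11 and 16855 in DRG, whereas Piezo1 was higher in F-11 at 252 against 7.48 CPM. Of 18 neuropeptide and nociceptor signalling genes, 16 were lower and 1 was higher, and Tac1, the substance P precursor gene, had 3 counts against 9274. The neurofilament genes Nefm and Nefh had log2 ratios of -5.71 and -4.38. These ratios use mouse counts only. Nefm had 3708 mouse and 6577 rat counts in F-11, and Nefh had 6191 and 967. On rat genes, Scn10a, Scn11a, Trpv1 and Calca had 5, 4, 1 and 9 counts in F-11.

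The pan-neuronal list had a median of -3.11, with 21 of 30 members lower and 0 higher, and the sensory identity list -4.54, with 19 of 30 lower and 1 higher. The purinergic receptor list had -3.69 and the GABA and glycine receptor list -6.2. Some receptor and neuronal genes nevertheless lay within 4-fold of DRG in F-11. The ATP receptor gene P2rx3 had 60.3 against 232 CPM, a log2 ratio of -1.94 that became -2.22 with TMM factors and -2.24 with DESeq2 factors, past 4-fold lower. Prph, which encodes peripherin, had 1365 against 1739 CPM. Htr3a, a serotonin-gated channel gene, stood at 358 against 177 CPM, and Chrnb2, a nicotinic receptor subunit gene, at 89.9 against 156 CPM. Th, the gene of tyrosine hydroxylase, had 76.8 against 73.2 CPM, a log2 ratio of 0.07 that became -0.21 with TMM factors. The calcium channel list had a median of -1.58 over 15 members, 6 of them lower and 3 higher, and Cacnb3 stood at 114 against 311 CPM. The nicotinic and muscarinic receptor list had a median of -2.48, which lay at percentile 10.38 of matched lists, and the HCN and chloride channel list had -1.07 at percentile 3.95.

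Genes of other cells in the ganglion were low in F-11. Of 20 Schwann cell and myelin genes, 19 were lower with a median of -6.08. Of 14 satellite glia genes, 12 were lower with a median of -7.30, and Apoe stood at 4.67 against 2408 CPM. The endothelial, macrophage, fibroblast and erythroid lists had medians of -5.54, -4.96, -5.44 and -4.61. These cell types are part of the DRG library, so its CPM values for neuronal genes are shares of a mixed tissue. Fbln1 and Fbln2, matrix genes, went the other way, at 731 against 6.13 CPM and 630 against 133 CPM. The Fbln2 log2 ratio of 2.24 became 1.96 with TMM and 1.94 with DESeq2 factors, under 4-fold. Of 30 division genes, 28 were higher with a median of 5.41, and Top2a stood at 1163 against 3.79 CPM. Of 21 sympathoadrenal genes, 15 were higher and 2 lower with a median of 4.27, and Chga was lower at 12.6 against 306 CPM. The 6 highest ratios belonged to Asz1, Xist, Gm364, Dkk1, Dlx2 and Sohlh2. Dlx2 had 2736 counts in F-11 and 0 in DRG, at least 1124-fold higher. The 6 lowest belonged to Piezo2, Fxyd2, Lifr, Tac1, Scn11a and Slc6a17. Under TMM and DESeq2 factors the median log2 ratio of all genes fell by 0.30 and 0.33, so each ratio of F-11 to DRG is lower by about that much on those scales.

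**Figure D1:**
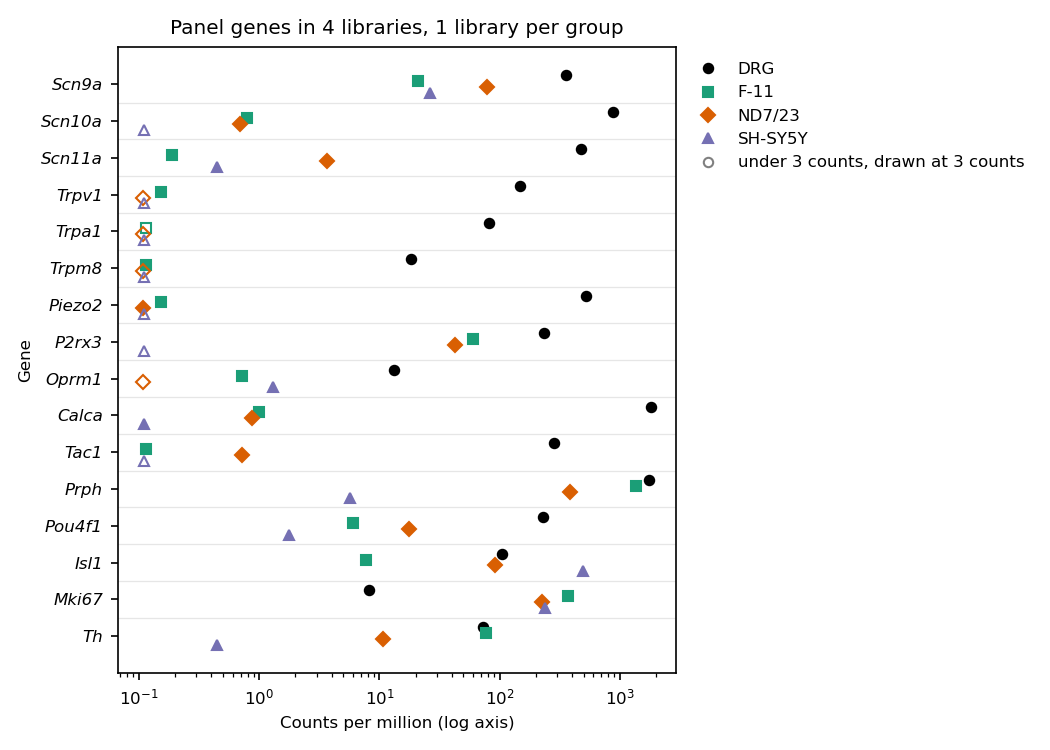
CPM of 16 panel genes on a log axis, 1 point per library, with open symbols for genes under 3 counts, drawn at the level of 3 counts. Scn10a lies at 870 CPM in DRG and under 1 CPM in each line, while Mki67 lies at 8.25 CPM in DRG and between 223 and 367 CPM in the lines.

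ND7/23 was compared with DRG in the same way. Scn10a and Calca were again under 1 CPM. The sensory identity list had a median of -3.62, with 22 of 30 members lower, 0 higher and 8 within 4-fold. Isl1, a transcription factor gene of sensory neurons, stood at 91.9 CPM in ND7/23 and 105 CPM in DRG, with a log2 ratio of -0.19 (interval -0.27 to -0.12). Scn9a stood at 77.8 against 356 CPM. Scn10a had 0.687 CPM and Calca 0.867 CPM in the line. Chrna3, a nicotinic receptor gene of autonomic neurons, was higher at 414 against 27.8 CPM.

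Across 15683 genes, 3169 were 4-fold higher and 3037 were 4-fold lower in ND7/23. With TMM factors the split was 2234 higher and 3556 lower, so which direction held more genes depended on the scaling, which moved the median of all genes by -0.47. Of 14 sodium channel genes, 10 were lower and 1 was higher, with a median of -5.51. Of 67 potassium channel genes, 44 were lower and 2 were higher, with a median of -4.17. Scn11a stood at 3.65 against 473 CPM. Trpv1 and Trpa1 each had 1 count, and the cold-gated channel gene Trpm8 and the opioid receptor gene Oprm1 each had 0 counts. Oprm1 was at least 122-fold lower and Trpm8 at least 169-fold lower than in DRG. Glrb, a glycine receptor subunit gene, had 0 counts against 9822 and was at least 2789-fold lower. P2rx3 stood at 42.4 against 232 CPM. Asic1, an acid-sensing channel gene, was within 4-fold at 130 against 200 CPM, as was Clcn3 at 118 against 176 CPM. The cannabinoid receptor gene Cnr1 was higher at 485 against 61.5 CPM, and Htr3a was lower at 36.6 against 177 CPM.

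Division genes were higher in 27 of 30 cases with a median of 4.81, and sympathoadrenal genes in 16 of 21, with 2 lower and a median of 4.28. Chgb, which encodes a secretory granule protein, stood at 2675 against 238 CPM, and Hand2 at 858 against 0.77 CPM. Phox2a had 4457 counts against 3, a log2 ratio of 10.77 (interval 9.22 to 13.05). Schwann cell genes were lower in 18 of 20 cases with a median of -5.11, and satellite glia genes in 11 of 14 with a median of -7.12. Pan-neuronal genes had a median of -2.75 over 30 members, 20 of them lower and 0 higher, and Tubb3 and Snap25 had log2 ratios of -2.90 and -4.02. Prph stood at 384 against 1739 CPM, a log2 ratio of -2.18 that became -1.98, under 4-fold, with mouse and rat counts summed. The 6 lowest ratios belonged to Piezo2, Vwa5a, Atp11a, Cntn1, Slc9a9 and Glrb, and the other high ratios to Pet2, Asz1, Gm364, Rpl39l and Dlk1. Des, an intermediate filament gene of muscle, was higher at 24.6 against 2.52 CPM.

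SH-SY5Y was compared with DRG over matched human and mouse symbols, so species, annotation and cell differences are joined in each ratio. The line was far from the ganglion in sensory genes and high in sympathoadrenal ones. Dbh, the gene of the enzyme that makes noradrenaline, stood at 4673 against 0.246 CPM, and Dlk1 at 6848 against 0.339 CPM. Isl1 was higher at 492 against 105 CPM, a log2 ratio of 2.22 that became 1.9 with TMM and 1.86 with DESeq2 factors, under 4-fold. Th was lower at 0.443 against 73.2 CPM. P2rx3 had 1 count and Trpa1 had 0 counts in the line. Rgs5, a pericyte gene on the endothelial list, reached 10632 against 208 CPM.

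Of 12385 genes, 2704 were 4-fold higher and 2915 were 4-fold lower. At 2-fold the order turned, with 4567 higher and 3953 lower. TMM factors moved the median log2 ratio of all genes by -0.35. The sensory identity list had a median of -6.41 over 31 members, 26 of them lower and 2 higher, and Nefm and Nefh had log2 ratios of -9.30 and -8.78. Prph stood at 5.64 against 1739 CPM. Of 14 sodium channel genes, 11 were lower and 2 higher with a median of -5.96, and Scn9a stood at 26.2 against 356 CPM. Of 67 potassium channel genes, 54 were lower and 6 higher with a median of -5.12, and Kcna1 had 0 counts against 27087, at least 7538-fold lower. Calca had 3 counts and Scn10a 1 count in the line. Cacna2d2, a calcium channel subunit gene, was higher at 1050 against 41.9 CPM, as were the receptor genes Chrna3 at 1136 against 27.8 CPM, Chrm3 at 156 against 3.57 CPM and Ptger2 at 130 against 1.88 CPM. Sympathoadrenal genes were higher in 17 of 23 cases, with 2 lower and a median of 6.29, and division genes in 27 of 30 with a median of 5.68. Schwann cell and satellite glia lists had medians of -7.08 and -8.47. The fibroblast list had a median of -0.26 at percentile 17.78, with 6 members higher and 6 lower, and the collagen gene Col3a1 stood at 686 against 98.9 CPM.

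Among the 6 highest ratios, mt-Co2 was listed at 0 and mt-Nd4l at 3 counts in DRG, although every cell uses both genes, so those ratios describe the tables. The others were Dlk1, Dbh, Phox2a and Prame. The 6 lowest were Sncg, Calca, Prune2, Scn10a, Parm1 and Kcna1. The ribosomal protein list had a median of 4.92, against 2.58 in F-11 and 2.69 in ND7/23. The reference housekeeping list had a median of 1.24 at percentile 99.13, against 0.35 in F-11 and 0.57 in ND7/23.

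**Figure D2:**
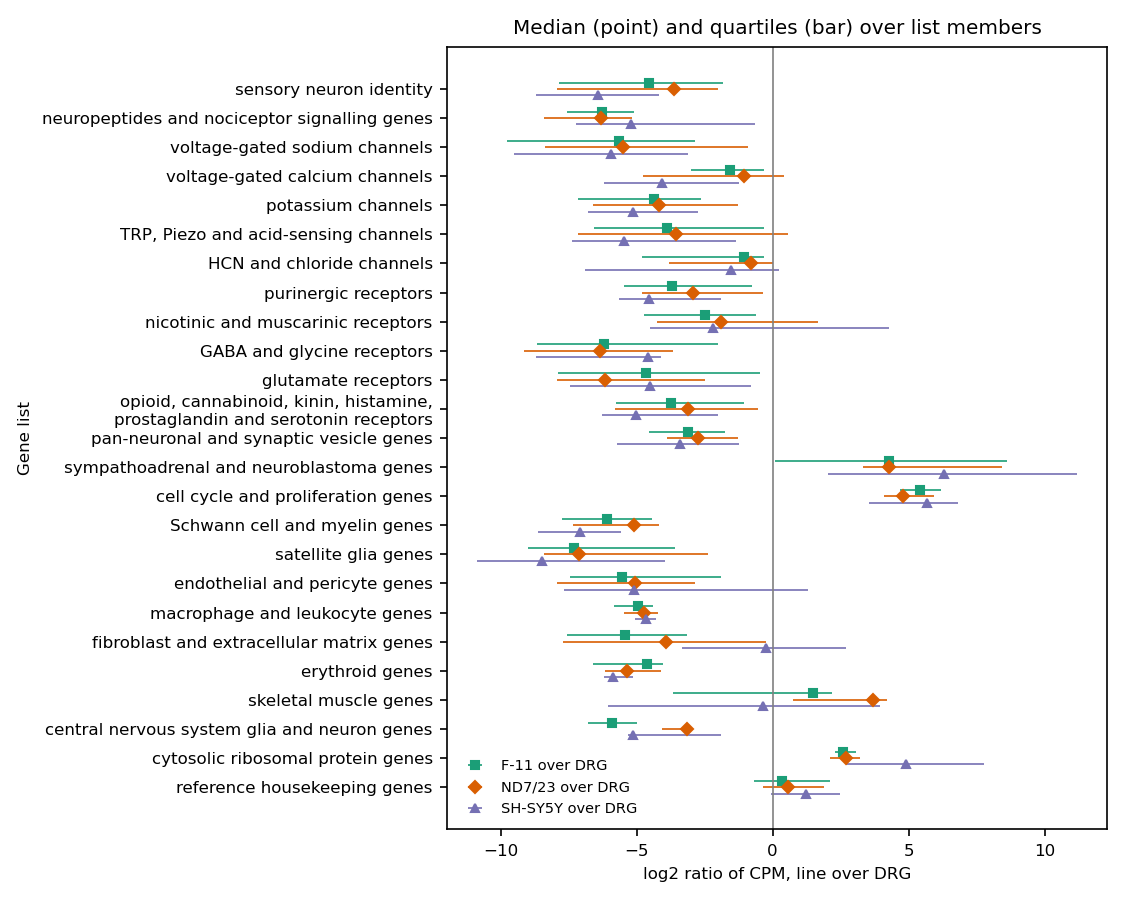
Median (point) and quartiles (bar) of the log2 ratio of CPM, line over DRG, over the measured members of each of the 25 gene lists. The division list lies between 4.81 and 5.68 and the satellite glia list between -8.47 and -7.12 in the 3 lines.

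The 10 channel and receptor lists were also read as presence or absence, since a line is often chosen for a single channel. Of 213 such genes at 1 CPM in DRG, 105 reached 1 CPM in F-11 (49.3%, interval 42.4 to 56.2), 114 in ND7/23 (53.5%, 46.6 to 60.4) and 103 in SH-SY5Y (48.4%, 41.5 to 55.3). The same 213 genes enter each share, and the difference between lines was not tested. For the hybrid lines these counts use mouse genes only. With 1 CPM on mouse or rat genes, 121 of 213 (56.8%) were detected in F-11 and 121 of 213 (56.8%) in ND7/23. Calcium channels were kept most often in F-11, 13 of 15, and in ND7/23, 12 of 15, while SH-SY5Y held 9 of 15. GABA and glycine receptor genes were kept in 5, 2 and 4 of 14 cases. The share depended on the threshold, with 71.5% of genes in F-11 at 0.1 CPM and 37.7% at 5 CPM. Asic4 and Chrna5, found after their values were seen, reached 1 CPM in each line but not in DRG, where they had 0.616 and 0.462 CPM. Some counts near the threshold were small next to DRG: Calca in F-11 had 26 counts, which is 0.0444% of its DRG count.

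Levels in F-11 and ND7/23 were closer to each other across genes than to those in DRG. Both lines are hybrids of mouse neuroblastoma cells and rat DRG neurons, so their likeness is not that of lines with unrelated origins. Spearman's rho across genes was 0.901 between them, 0.589 for F-11 and DRG, and 0.610 for ND7/23 and DRG. For SH-SY5Y and DRG it was 0.428, over 12385 human and mouse genes matched by symbol. Species and annotation enter that value, so it does not rank SH-SY5Y against the hybrids. Genes are not independent replicates. Of 14127 genes, 586 were 4-fold higher and 1296 were 4-fold lower in F-11 than in ND7/23, and TMM factors moved the median of all genes by 0.12. In the rat tables the split was nearer to even, with 928 of 11036 genes higher and 1006 lower. Th was higher in F-11 at 76.8 against 10.8 CPM and Htr3a at 358 against 36.6 CPM. Chrna3 was lower at 7.02 against 414 CPM, Isl1 at 7.71 against 91.9 CPM and Chgb at 145 against 2675 CPM. Cnr1 stood at 39.1 against 485 CPM.

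The potassium channel list was lower in F-11 than in ND7/23, with a median of -1.46 at percentile 0.17, 16 members lower and 7 higher. The nicotinic and muscarinic list had a median of -1.98 at percentile 0.32, with 5 of 10 members lower and 1 higher. The sodium channel list had a median of -1.41 at percentile 1.22, with 2 of 9 members lower, 0 higher and 7 within 4-fold. Scn9a, at 21.0 against 77.8 CPM, was within 4-fold. The GABA and glycine receptor list went the other way, with a median of 1.47 at percentile 98.3. Of its 8 measured members, 2 were higher and 2 lower. Division genes had a median of 0.51 at percentile 99.99, with 30 of 30 members within 4-fold. Oprm1 had 19 mouse counts in F-11 and 0 in ND7/23, under 1 CPM in both, but 84 and 0 counts on the rat gene. With mouse and rat counts summed it was called higher in F-11, with a log2 ratio of 5.09, in which the 0 counts of ND7/23 were set to the floor of 3. The genes with the highest ratios were Prr9, Ctla2a, Tm4sf1, Car6, Avil and Crabp1, and those with the lowest were Lrg1, Ephb2, Creg2, 5730469M10Rik, Capn6 and Bai1. Ephb2 had 0 counts in F-11 and 2222 in ND7/23, at least 705-fold lower. Avil, which encodes the sensory neuron protein advillin, stood at 239 against 2.13 CPM.

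Gene calls against DRG overlapped between lines. F-11 and ND7/23 shared 2105 higher and 2654 lower genes, where independent lists would share 485.3 and 703.7. F-11 and SH-SY5Y shared 1065 and 1778, against 342.7 and 695.3, and ND7/23 and SH-SY5Y shared 1201 and 1657, against 383.4 and 593.2. Simulated unchanged lines shared 0 calls, but they held counting error only, which the 4-fold rule did not call, and so leave variation of the DRG library untested. In each of the 3 lines together, 917 genes were higher and 1484 lower. All of these use the same DRG library, so part of the excess may come from that library. F-11 and ND7/23 also share their kinds of parent cell, which the numbers for independent lists do not allow for.

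The rat tables count reads on genes of the rat, the species of the other parent of the hybrids; reads that also align to the mouse genome may be among them. Over the 15773 genes in both tables, rat counts made up 31.98% in F-11 and 28.90% in ND7/23. Over single genes with 20 or more counts the median rat share was 30.1% in F-11 and 25.5% in ND7/23. In the same order, 206 and 162 genes had over 90% rat counts, and 251 and 384 had under 1%. Rat mitochondrial genes had 27 and 102 counts, against 266440 and 594008 on mouse mitochondrial genes. P2rx3 had 1589 mouse and 754 rat counts in F-11, and Prph had 35958 and 17931. Nefl and Thy1, chosen after their values were seen, leaned to rat genes in F-11, with 364 mouse and 1457 rat counts for Nefl and 18 and 2045 for Thy1. In ND7/23 Thy1 had 404 mouse and 2 rat counts, whereas Nefl leaned to the rat gene there too, with 672 mouse and 2812 rat counts.

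Rat-to-mouse ratios differed between the hybrids by mouse chromosome in GRCm38.p6 order. The median of log2(rat/mouse counts), F-11 minus ND7/23, was 0.80 over 436 genes of chromosome 6 and 0.84 over 318 genes of chromosome 12. It was -0.66 over 302 genes of chromosome 13 and -0.40 over 423 genes of chromosome 3. On chromosomes 4, 11 and 18 it was 0.02, 0.03 and 0.02.

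**Figure D3:**
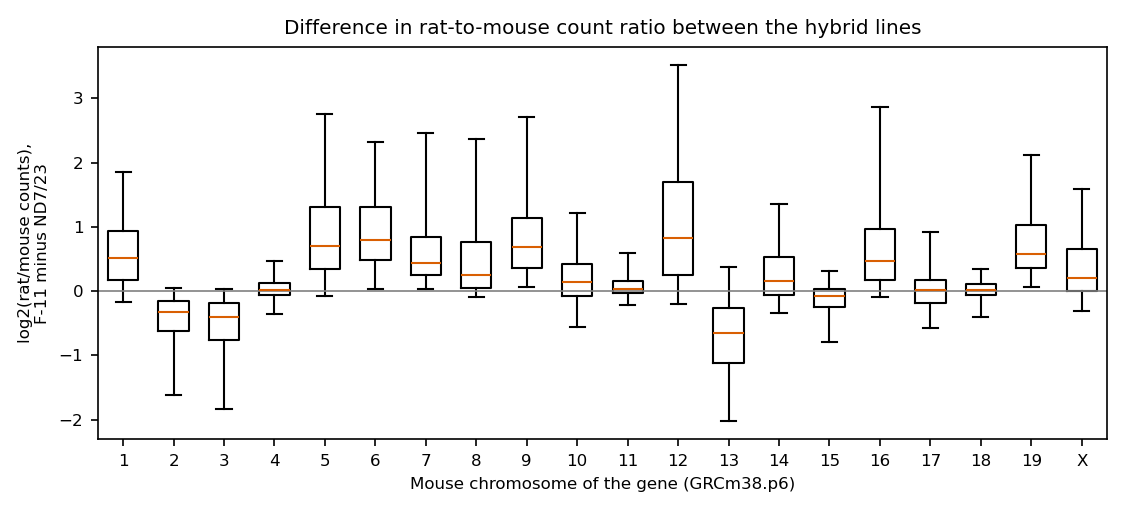
Difference in log2(rat/mouse counts) between F-11 and ND7/23 for 9012 genes, by mouse chromosome, with boxes for quartiles, coloured lines for medians and whiskers from percentile 5 to 95. Chromosomes 6 and 12 lie above 0 with medians of 0.80 and 0.84, and chromosome 13 lies below it at -0.66.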

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

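The genes below are those named in a comparison with DRG that were 4-fold higher than DRG in 1 line and 4-fold lower in another. Xist was left out of this search. With 1 library per line, the difference between lines was not tested. Ratios given as floor values come from under 3 counts, set to 3, and do not measure how low the gene lies. The log2 ratios to DRG of Isl1, a regulator of sensory and sympathetic neurons, were -3.77 in F-11 and 2.22 in SH-SY5Y, the latter 1.9 with TMM factors and so under 4-fold. Cacna2d2 had -2.15 in F-11 and 4.65 in SH-SY5Y. Chrm3, a muscarinic receptor gene, had -4.97 in F-11, a floor value of -5.04 in ND7/23 and 5.45 in SH-SY5Y. Cnr1 had 2.98 in ND7/23 and a floor value of -9.12 in SH-SY5Y. Ptger2, a prostaglandin receptor gene, had a floor value of -4.04 in F-11, -3.11 in ND7/23 and 6.11 in SH-SY5Y. Among genes of other cell types, Rgs5 had -8.96 in F-11, -2.44 in ND7/23 and 5.67 in SH-SY5Y. Col3a1 had -8.76, a floor value of -9.83 and 2.79 in the same order. Fbln2 had 2.24 in F-11, under 4-fold at 1.96 with TMM factors, and -2.82 in SH-SY5Y. Des had 3.28 in ND7/23 and -4.51 in SH-SY5Y. Ratios of SH-SY5Y also hold the difference between human and mouse gene models.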

How the results depend on the processing

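No paired analysis was possible because each group has 1 library and the groups share only the number 1. Among the counts, shares and correlations, 95 values under alternatives stayed close to the reported ones and 30 moved. No called named gene, and no list outside the central 95% of random lists, changed sign under the alternatives run for it. Of 107 values for other lists, 7 changed sign: the sensory identity list in F-11 against ND7/23, for example, had -0.09 and, with TMM factors, 0.03. For called genes under the scaling factors, a kept sign is a weak check. A call needs 4-fold, while the median log2 ratio moved by -0.5 in ND7/23 against DRG with DESeq2 factors. Some calls of named genes did change. In F-11 against DRG with TMM factors, Chrna7 went from -1.82 to -2.1 and became lower. Actb went from 2.24 to 1.97 there and was no longer called. In F-11 against ND7/23, Glul went from -2.04 to -0.7 with mouse and rat counts summed. Restricting the hybrids to mouse counts of genes in both tables was chosen after the data were seen.

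A fold of 2 in place of 4 gave, by construction, more genes: 5375 higher and 4857 lower for F-11, 6049 and 4237 for ND7/23, and 4567 and 3953 for SH-SY5Y against DRG. More were then higher than lower in F-11 and SH-SY5Y too, as with the 5 CPM filter in SH-SY5Y, at 2437 and 2285. For F-11 against ND7/23 it gave 1444 higher and 2752 lower. A filter of 5 CPM left 324 higher and 782 lower genes in that comparison, since fewer genes enter. Over all genes, rho was 0.864, 0.865, 0.660 and 0.937 for F-11, ND7/23 and SH-SY5Y against DRG and for F-11 against ND7/23, because genes silent in both libraries enter. Over genes at 1 CPM in both libraries it was 0.571, 0.370 and 0.897 for F-11 and SH-SY5Y against DRG and for the hybrids. Pearson's r was 0.571, 0.580, 0.402 and 0.881 in the first order; the cause was not tested.

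The share of DRG-detected channel and receptor genes also detected was 71.5%, 68.7% and 66.3% in F-11, ND7/23 and SH-SY5Y at 0.1 CPM, and 37.7%, 42.3% and 32.6% at 5 CPM. At 10 reads it was 59.3% in F-11 and 59.3% in ND7/23. With mouse or rat genes counted it was 56.8% in F-11 and 56.8% in ND7/23. The rat share was 32.03% in F-11 and 29.11% in ND7/23 without the 50 most abundant genes, and 30.1% and 25.45% as a median over genes; the cause was not tested. Of the list medians, 332 values stayed within the bootstrap interval over members with the same place among random lists, and 31 did not. Of the named genes' ratios, 1535 stayed within the counting interval and 410 did not. Depth limits genes under 3 counts. The correction for gene length in SH-SY5Y was not run.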

Other observations

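All tests in this part were chosen after the results were seen, except that of rat chromosome segments. The list members in this paragraph are not described in the report and were chosen after their values were seen. Fabp7 and Sox10, genes of satellite glia and Schwann cells, stood at 312 and 29.9 CPM in DRG. They had 0.266 and 0.076 CPM in F-11, 0.181 and 0.904 CPM in ND7/23, and 0 and 0.037 CPM in SH-SY5Y. The receptor tyrosine kinase gene Ret was abundant in each library, at 1020 CPM in DRG, 1084 in F-11, 3038 in ND7/23 and 3870 in SH-SY5Y. Gata3, a sympathoadrenal regulator, stood at 0.062, 36.9, 32.3 and 269 CPM in the same order. Npy, which encodes neuropeptide Y, stood at 0.523, 223, 70.9 and 188 CPM. Pou4f2 was higher in F-11 than in DRG, at 188 against 12.9 CPM, and Runx1 was lower, at 3.38 against 48.9 CPM.

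The first pattern is the rat-table counts of F-11 and ND7/23, which differ between the lines in runs of neighbouring genes. If mouse transcripts that also align to the rat genome made up all rat counts, the difference between the lines should not follow gene order, but its correlation between neighbours was 0.668, and the highest of 1000 shuffled orders gave 0.035. Different copy numbers of rat chromosome segments in the lines may account for part of it: the log2 ratio of rat counts correlated 0.349 between neighbours, against 0.19 for mouse counts. Whether rat transcripts also add to the mouse counts cannot be told apart, since rho over 20 chromosomes was -0.39 and the mouse counts stand in both measures, which pulls it down. Cross-aligned mouse reads in part of the rat counts stay open, and so do mouse copy numbers, given the 0.19, and regulation of whole domains, which was not tested.

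Another pattern is the high ribosomal protein list in SH-SY5Y. Scaling by the total is argued against, since the median log2 ratio was 4.60 with TMM factors. Reads shared with processed pseudogenes and missing from the mouse tables may account for part: the SD of log2 ratios to F-11 over the list was 6.34 times that of F-11 to ND7/23, and 25 of 38 genes lay under 10 CPM in DRG, 11 in F-11, 13 in ND7/23 and 1 in SH-SY5Y. The reference housekeeping list gave 4.24 on the same measure, and it holds genes such as Gapdh with copies of their own, so the test does not separate this from other human and mouse differences. Higher levels in dividing lines also stay open, since the list had a median of 2.58 in F-11, on mouse genes in both libraries.

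The last pattern is the trace counts of abundant DRG transcripts in the hybrid lines. In F-11, Calca had 0.0444% of its DRG count, Scn10a 0.0743% and Piezo2 0.0237%. A single rate of read carry-over from the DRG library as the source of all such traces is argued against. Over 59 genes with 5000 or more DRG counts and under 1 CPM in both lines, the dispersion of counts around 1 percentage (chi-square per degree of freedom) was 6.26 in F-11 and 9.27 in ND7/23, against at most 1.7 in 1000 simulations of counting error. For the 7 with 20000 or more DRG counts, Calca and Scn10a among them, it was 0.97 and 2.69, against simulated values of at most 3.63 and 4.05 with 2.69 in their upper tail, so carry-over cannot be told apart from low expression or rat reads on mouse genes, which were not tested here.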
